A study of Mus musculus with 5 samples.

How the data were processed

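Single-cell RNA was measured in 5 droplet libraries of mouse skin, 1 library for each of 5 groups: untreated wild-type dermis, untreated wild-type epidermis, wild-type dermis after imiquimod, non-lesional epidermis of K5. Pp6fl/fl mice and lesional whole skin of K5. Pp6fl/fl mice. Per the labels, the wild-type mice were C57BL/6, tissue was digested with enzymes, dead cells were removed by FACS and libraries were made with the Chromium Single Cell 3′ v3 kit. Per the submitters' processing notes, CASAVA and Cell Ranger were run against mm10, with no versions given, and the matrix headers give a software version of 3.0.2. The deposited values are UMI counts (unique molecular identifiers, 1 per captured transcript molecule) for 31053 genes in each called cell barcode, with no normalization. How the authors called cells is not given in the sources used here.

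From these counts, barcodes with at least 200 detected genes and under 20% of UMIs from mitochondrial genes were kept. Doublets were scored per library with Scrublet, and the top-scoring barcodes were removed in a share that grew with the barcodes of the library (2 in the untreated dermis, 215 in the imiquimod dermis). All 5 libraries were then clustered jointly without batch integration, on counts per 10000, 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0. Cells with at least 10% haemoglobin UMIs were set apart as erythroid. The 31 clusters were named as cell classes from 23 marker lists. A class needed a marker score of at least 0.25 and at least 3 markers detected in a share of at least 0.2 of its cells. Clusters with a second class at 0.7 of the best score or more were treated as mixed. Of 13288 barcodes, 11577 cells remained. The class names rest on these markers alone.

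UMIs were summed over the cells of a class in a library and scaled by the class total to give CPM values. Errors of a CPM are exact Poisson 95% intervals, those of a share are exact (Clopper-Pearson) binomial 95% intervals (for 0 cells, the limit given is 3 counts of the total), and those of a ratio between libraries are exact intervals from the conditional binomial. They cover counting error only. Each group has 1 library, so no test between groups was run, no difference has a replicate check, and no number of changed genes is given. Where a library had 0 UMIs of a gene, the fold is a lower bound against 3 counts over the class. Classes with fewer than 20 cells in either library were not compared.

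Before the data were examined, 5 comparisons, 28 gene lists and the rule for naming genes were fixed, with 14 alternative settings. A list member was measured with at least 10 UMIs over both libraries and at least 10 CPM in either. It was called higher or lower only by size, where the interval of its ratio lay wholly beyond 1.5-fold. The list value is the median log2 ratio with a pseudocount of 5 CPM, and it was set against 10000 random lists matched on expression in 20 bins. Genes were named where they reached 50 CPM in the higher library, their interval lay wholly beyond 2-fold, and no other class of at least 20 cells in that library had over 10 times the CPM, which guards against free RNA. In the untreated dermis only macrophages and monocytes, T cells and ILCs and dendritic cells reached 20 cells. In the untreated epidermis only keratinocytes and T cells and ILCs did. For genes higher in these libraries the guard could not catch RNA of other classes. Mitochondrial, ribosomal protein, haemoglobin, predicted, Xist and Y-linked genes were left out, and the 10 highest and 10 lowest by log2 ratio were taken. For each list described, 2 to 4 members with the largest ratios are examples. Ppp6c, Arg1, Odc1, Srm, Sms, Cebpb, Il17a, Il17f, Il23a, Il1b, Tlr7, Krt6a, Krt16, S100a8 and S100a9 are always given in the class that holds them. The wild-type dermis gave too few fibroblasts for the rule, so the classes and genes named for the lesional skin against untreated dermis were chosen after their values were seen, as were all values within single clusters and, among matrix genes, Col1a1 and Col3a1.

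The naming step was tested on simulated counts of the real genes and libraries, with 200 genes changed by known folds. At 5-fold, 100% were recovered in each of the 5 comparisons. At 2.5-fold, 71.7% were recovered for macrophages with imiquimod (2229 genes run), 70.7% for keratinocytes of the non-lesional epidermis (2395 genes), 100% for lesional keratinocytes (2605 genes), 61.0% for lesional macrophages against untreated dermis (2545 genes) and 90.9% for fibroblasts of the lesional skin against imiquimod (2619 genes). No unchanged gene was named, and 94.4% to 95.4% of the intervals held the true ratio. These rates hold for the simulated counts and say nothing on differences of preparation between single libraries, which have no replicate here.

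The alternatives changed the cell filter (at least 500 genes and under 10% mitochondrial UMIs, or all barcodes), doublet removal, the clustering resolution (0.5 and 2.0), the naming of classes, the scaling (TMM factors of edgeR), the pseudocount (1 and 20 CPM), the minimum of UMIs (none and 50), sums against means of cells, depth (thinning to 2000 UMIs per cell) and free RNA (an estimated free RNA profile subtracted). After the data were seen, 8 more were added. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 were used.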

Results

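Gene expression was counted in single cells of mouse skin in 5 libraries, 1 per group. Wild-type C57BL/6 mice of 10 weeks gave untreated dermis, untreated epidermis, and dermis after 5 days of imiquimod on the ear, a TLR7 agonist cream used to induce psoriasis-like inflammation. K5. Pp6fl/fl mice gave non-lesional epidermis at 10 weeks and psoriasis-like lesional whole skin at 18 weeks. Ppp6c encodes the catalytic subunit of protein phosphatase 6. The untreated dermis library held 3020790 UMIs and 519 filtered cells with a median of 4588 UMIs per cell. The untreated epidermis held 3946755 UMIs and 898 cells (median 3382), and the imiquimod dermis 41258087 UMIs and 4776 cells (median 6470.5). The lesional skin held 34376558 UMIs and 2579 cells (median 8179), and the non-lesional epidermis 21640310 UMIs and 2805 cells (median 4972). The body site of the untreated and K5.Pp6 mice is not given in the sources used here, so a difference of site could not be separated from the groups. There were no replicates, so each difference below holds between a pair of libraries, and its interval covers counting error only.

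Neutrophils made up 14.8% (13.8 to 15.8) of the imiquimod dermis (707 of 4776 cells) and 2.87% (2.26 to 3.59) of the lesional skin, against 0 of 519 cells of the untreated dermis, which allows a share of up to 0.578%. Macrophages and monocytes were 48.7% (44.4 to 53.1) of the untreated dermis, 51.1% (49.6 to 52.5) of the imiquimod dermis and 10.5% (9.39 to 11.8) of the lesional skin. T cells and innate lymphoid cells (ILCs) were 26.6% (22.8 to 30.6) of the untreated dermis, 7.83% (7.08 to 8.63) of the imiquimod dermis and 18.7% (17.2 to 20.2) of the lesional skin, and 40.6% (37.4 to 43.9) of the untreated epidermis. Fibroblasts were 26.1% (24.4 to 27.9) of the lesional skin, 7.39% (6.66 to 8.17) of the imiquimod dermis and 3.08% (16 cells) of the untreated dermis. Keratinocytes were 48.7% (45.3 to 52.0) of the untreated epidermis and 16.2% (14.8 to 17.6) of the lesional skin. Digestion and sorting set these shares together with the tissue.

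**Figure D1:**
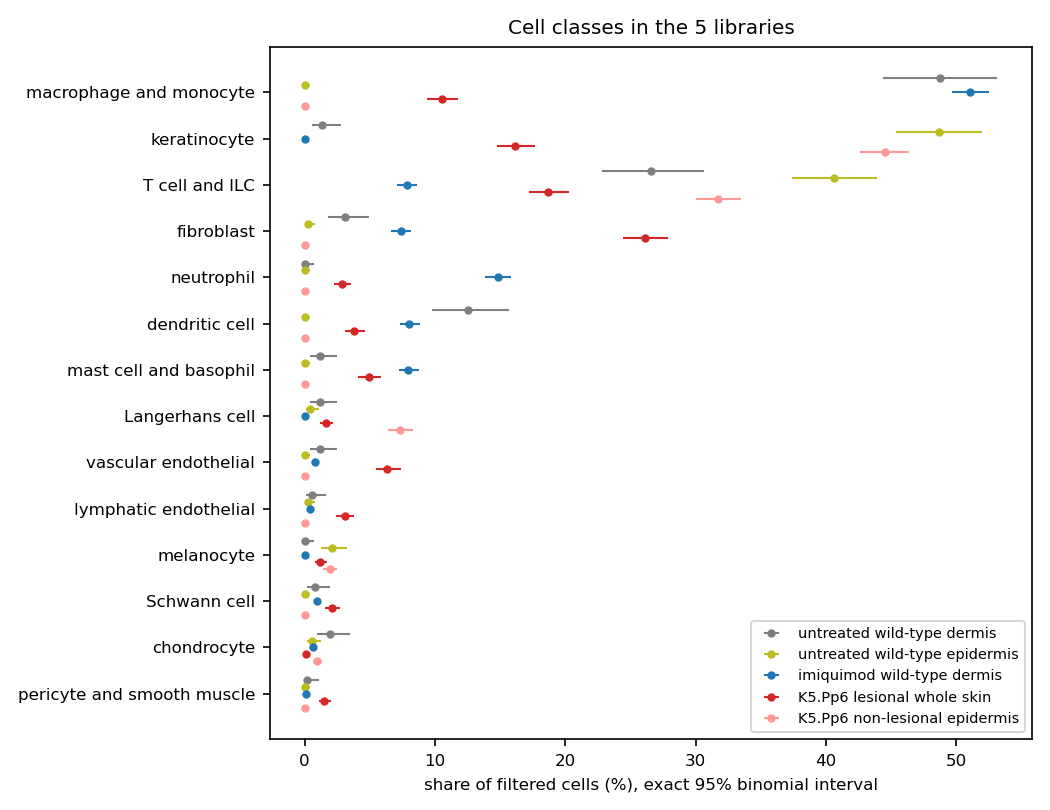
Share of filtered cells (%) in each of 14 cell classes for the 5 libraries, with exact binomial 95% intervals as error bars. Neutrophils reach 14.8% in the imiquimod dermis and 2.87% in the lesional skin, and fibroblasts reach 26.1% in the lesional skin.

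Ppp6c, the gene named in the genotype, was detected in keratinocytes of every library that held them in number. It stood at 85.3 CPM (72.3 to 100.09) in the untreated epidermis, 72.2 CPM (67.6 to 77.1) in the library labelled K5.Pp6 non-lesional epidermis and 50.5 CPM (46.4 to 54.9) in the library labelled K5.Pp6 lesional whole skin. The ratio of non-lesional to untreated epidermis was 0.847-fold (0.712 to 1.01), and that of lesional to non-lesional skin was 0.699-fold (0.628 to 0.777). T cells and ILCs, given as a background, had 81.2 CPM in the untreated epidermis, 94.2 CPM in the non-lesional epidermis and 52.3 CPM in the lesional skin. Ppp6c (ENSMUSG00000026753) lies on chromosome 2 from 39194354 to 39226451 (mm10), with a 3′ UTR from 39194354 to 39197343. The libraries read 3′ ends, and the deleted part of the gene is not given in the sources used here, so these values check nothing about the genotype.

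Imiquimod dermis was compared with untreated dermis, the comparison of the treatment in wild-type mice. In its T cells and ILCs, 3 cytokine genes of type 17 lymphocytes were far higher, while the effector list that holds them went both ways. Il22, whose protein acts on keratinocytes, was at 3143 CPM against 8.49 CPM (370.3-fold, 145 to 1359), Il17f at 2635 against 29.7 CPM (88.7-fold, 52.8 to 162) and Il17a at 1151 against 95.5 CPM (12.1-fold, 8.99 to 16.6). Macrophages and monocytes were lower in all 25 measured genes of resident dermal macrophages (median log2 ratio −2.58, −2.65 to −2.49) and higher in 16 of 31 inflammatory genes, with 5 lower (median 0.93, 0.65 to 1.15).

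Among the resident genes, Retnla was 360.4-fold lower (198 to 731; 0.522 against 188 CPM), and the lectin genes Cd209d and Mgl2 were 20.5-fold (17.8 to 23.6) and 19.6-fold (17.2 to 22.4) lower. The chemokine gene Ccl24 was 11.3-fold lower (9.87 to 13.02). On the inflammatory side, Chil3 was at 992 against 19.7 CPM (50.4-fold, 34.6 to 76.4) and Plac8 was 20.9-fold higher (17.0 to 25.9). Plac8 stood at 1573 CPM in the neutrophils of the imiquimod library, so a part from free neutrophil RNA stays open, while Chil3 stood at 726 CPM there. The neutrophil genes Retnlg and S100a9 stood at 161 and 1179 CPM in these macrophages, against 12037 and 63505.5 CPM in those neutrophils. The inflammatory list was also higher in T cells and ILCs of the same pair of libraries (12 of 27 higher, 2 lower; median 1.68, 1.30 to 1.97). The chemokine genes Cxcl3 and Ccl2 were 2.38-fold (1.87 to 2.99) and 2.15-fold (2.02 to 2.28) lower. Of 26 type I interferon-stimulated genes, 10 were higher and 1, Oasl1, was 4.82-fold lower (3.47 to 6.60; list median 0.81, 0.65 to 0.98). Zbp1, a sensor of nucleic acids, was 18.1-fold higher (8.77 to 45.1) and the transcription factor gene Irf7 7.36-fold higher (3.86 to 16.1). Complement genes were lower in 8 of 11 and higher in 2 (median −1.43, −1.53 to −1.09), with C4b 10.9-fold (8.58 to 13.8) and C1qc 3.60-fold (3.47 to 3.73) lower. MHC class II presentation genes were lower in 8 of 13 (median −1.19, −1.24 to −1.08), among them Cd83 (13.9-fold, 12.2 to 15.8) and H2-Aa (2.87-fold, 2.79 to 2.95). Glycolysis genes were higher in 5 of 16 and lower in 1 (median 0.69, 0.55 to 0.79), with Gapdh 2.98-fold higher (2.80 to 3.17). The polyamine and arginine list was split, with 3 of 23 higher and 8 lower (median −0.61, −0.81 to −0.39; −0.33 relative to all genes and −0.27 relative to like length). Arg1, encoding arginase 1, was at 27.4 CPM against 0 (at least 12.5-fold higher) and Arg2 was 23.2-fold higher (6.39 to 192). Odc1, encoding the first enzyme of polyamine synthesis, was 0.414-fold (0.369 to 0.465) the untreated level. Srm was 1.196-fold (0.847 to 1.74), Sms 0.562-fold (0.436 to 0.736) and Cebpb 1.03-fold the untreated level. Il1b was 3.25-fold higher (2.92 to 3.62), and Tlr7, the receptor for imiquimod, was 0.280-fold (0.214 to 0.372) the untreated level. Il23a, at 3.09 against 0.730 CPM, was not clearly different (4.23-fold, 0.733 to 170).

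The 10 genes highest in macrophages and monocytes with imiquimod were Hp (142-fold, 55.4 to 520.5), Chil3, Fpr2, Vcan, Plac8, Ifitm6, Fcgr4, Acp5, Zbp1 and Sirpb1c. The 10 lowest were Retnla, Bc1, Cd209d, Mgl2, Cd209a, Cd83, Pmp22, Ramp3, Aqp1 and Lyz1. In T cells and ILCs, the 10 highest were Il22, Il17f, Ly6a (29.3-fold, 20.9 to 42.4), Gzma, Ifi27l2a, Il17a, Klra8, Gngt2, Gzmb and Gimap4. The 10 lowest were Klf4 (11.2-fold, 8.99 to 14.1), Bc1, Col27a1, Ccr8, Slc7a5, Crem, Slc16a10, Tnfsf11, Il5 (17.9-fold, 8.22 to 43.2) and Fermt2. Effector genes of T cells and ILCs went both ways, with 10 of 39 higher and 11 lower (median −0.44, −0.67 to −0.20), the γδ T cell gene Trdc 3.80-fold lower (3.49 to 4.13). Immediate-early and dissociation stress genes were lower in 18 of 35 and higher in 0 (median −0.76, −0.89 to −0.67; −0.46 relative to all genes). The effector list stood at −0.14 relative to all genes. In the same cells mitochondrially encoded genes were lower in 4 of 13 (median −0.61, −0.70 to −0.56) and keratinocyte stress and alarmin genes higher in 9 of 11 (median 2.20, 1.86 to 2.52). Dendritic cells were higher in 13 of 27 interferon-stimulated genes and lower in 1 (median 1.21, 0.96 to 1.47), with Ly6e 4.40-fold higher (3.55 to 5.53). They were lower in 12 of 27 genes of the integrated stress and unfolded protein response (median −0.72, −0.84 to −0.55), with Trib3 31.5-fold (16.2 to 67.2) and Chac1 18.5-fold (11.6 to 30.3) lower. Their keratinocyte stress and alarmin list, led by the neutrophil genes S100a8 and S100a9, was higher in 8 of 13 and lower in 1 (median 2.97, 2.46 to 3.18). Their resident macrophage list was lower in 9 of 20 and higher in 1 (median −0.75, −0.98 to −0.50).

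Other lists moved in the same macrophages. T cell and ILC effector genes were lower in 12 of 17 and higher in 4 (median −1.23, −1.46 to −1.06), and Cd3g stood at 9.36 against 59.1 CPM. Oxidative phosphorylation genes were higher in 19 of 73 and lower in 0 (median 0.52, 0.48 to 0.57). Mitochondrially encoded genes were lower in 4 of 13 (median −0.48, −0.51 to −0.40), and keratinocyte stress and alarmin genes were higher in 10 of 11 (median 1.89, 1.74 to 2.17). Immediate-early and dissociation stress genes were lower in 11 of 35 and higher in 0 (median −0.51, −0.55 to −0.45). The macrophages compared were not the same populations, since 84.2% of those of the untreated dermis lay in cluster 0 and those of the imiquimod dermis mainly in clusters 4, 3, 2 and 17. The median of all genes was −0.28 in macrophages and −0.30 in T cells, and the ratios fell with transcript length across genes (Spearman −0.35 and −0.32; genes are not independent replicates), with the resident list at −2.44 relative to genes of like length.

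**Figure D2:**
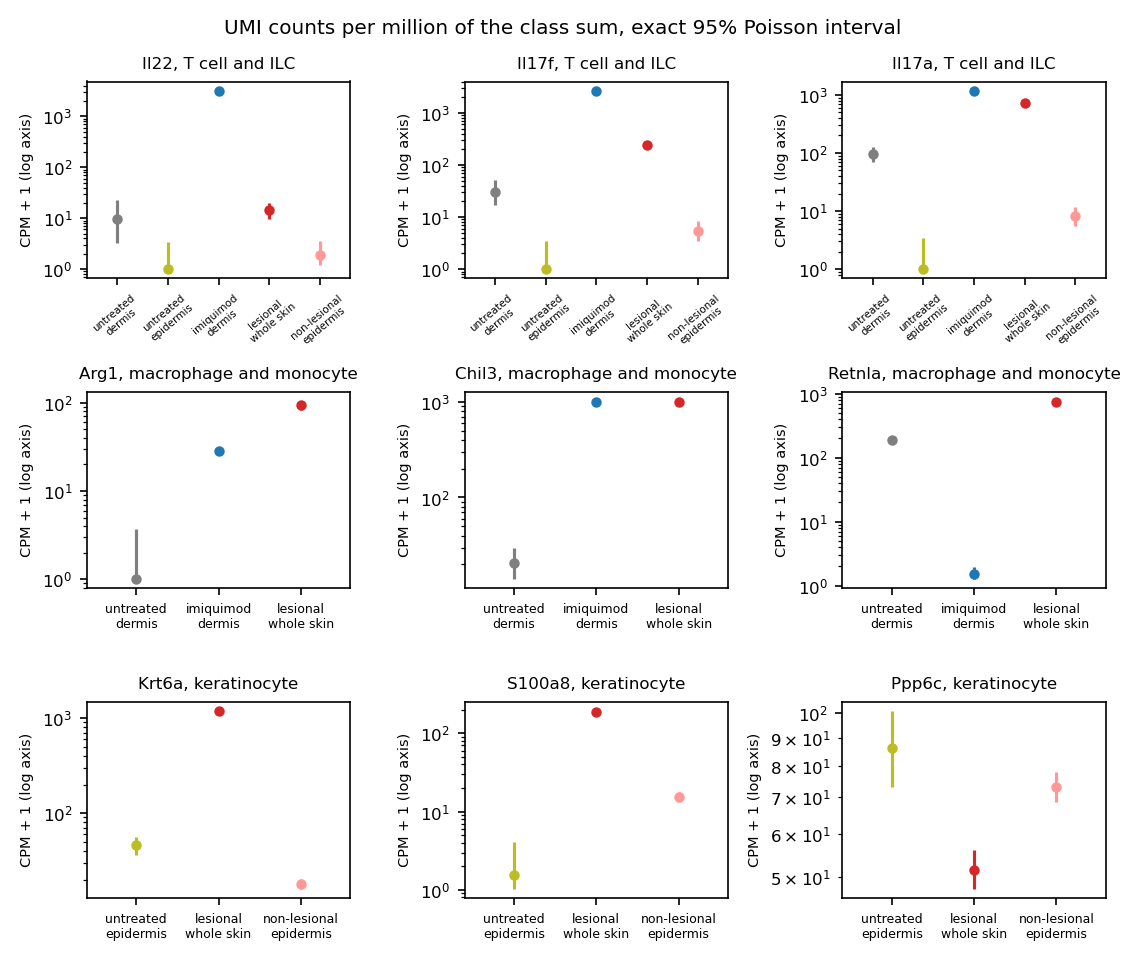
Level (CPM plus 1, log axis) of Il22, Il17f and Il17a in T cells and ILCs, Arg1, Chil3 and Retnla in macrophages and monocytes, and Krt6a, S100a8 and Ppp6c in keratinocytes, 1 point per library with exact Poisson 95% intervals. Il22 stands at 3143 CPM in the imiquimod dermis and 13.2 CPM in the lesional skin, and Retnla at 0.522 and 747 CPM.

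Non-lesional K5.Pp6 epidermis was compared with untreated wild-type epidermis, the comparison of the genotype without lesions. Cells of both libraries had like shares of mitochondrial UMIs in keratinocyte clusters 24 (856 against 46 cells, medians 3.17% and 2.72%) and 28 (hair follicle, 144 against 24 cells, medians 4.10% and 3.85%). The non-lesional cells held fewer UMIs in both, with medians of 11382 against 15482.5 and 3660 against 5811. These clusters were chosen after their values were seen. In cluster 24, 6 of 12 measured stress keratins and alarmins were higher and 0 lower (median 1.28, 0.87 to 1.63). In cluster 28, 0 of 9 were beyond 1.5-fold (median 0.18, 0.00 to 0.46). Krt17, a keratin of stressed epidermis and hair follicle, was 3.68-fold higher in cluster 24 (2.63 to 5.30), the fatty acid binding protein gene Fabp5 3.87-fold higher (2.40 to 6.67), Krt16 4.55-fold higher (2.19 to 11.4) and Il1f5 5.39-fold higher (1.82 to 26.4). The list was also higher in T cells and ILCs of this pair of libraries (5 of 9 higher, 0 lower; median 1.35, 0.89 to 1.77). Krt17 and Fabp5 stood at 218 and 130 CPM in those non-lesional T cells, against 183 and 93.3 CPM in cluster 24. Free RNA could therefore not be separated from these genes or from the list median. Krt16 stood at 15.6 against 45.3 CPM. Over all keratinocytes the same list stood near 0 (4 of 17 higher, 3 lower; median −0.01, −0.16 to 0.10), with Krt16 3.55-fold higher (2.52 to 5.15) and Krt6a 2.64-fold lower (2.01 to 3.43). Chemokine and cytokine genes were higher in 4 of 12 and lower in 1 (median 0.78, 0.58 to 0.99), and in T cells and ILCs of the same pair in 5 of 10 (median 0.95, 0.62 to 1.26). Ccl20, which draws CCR6-bearing cells, was 3.35-fold higher (2.45 to 4.70), Tgfb1 4.83-fold higher (2.99 to 8.35; 46.4 CPM, against 183 CPM in T cells) and Tslp 2.45-fold lower (1.87 to 3.19).

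Genes of the basement membrane and of basal adhesion had a median of −0.37 (−0.48 to −0.28) in cluster 24, with 2 of 24 higher and 2 lower. Igfbp3 was 1.90-fold (1.69 to 2.13) and Igfbp2 1.85-fold (1.62 to 2.10) lower. Polyamine and arginine genes had a median of −0.44 (−0.58 to −0.26) there with 0 of 20 beyond 1.5-fold.

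Over all keratinocytes, terminal differentiation genes were higher in 12 of 28 and lower in 4 (median 0.38, 0.18 to 0.58). The late cornified envelope genes Lce1m and Lce1a1 were 65.1-fold (11.6 to 2577) and 57.7-fold (10.3 to 2285) higher, each against 1 UMI. In T cells and ILCs of the same pair the differentiation list was higher in 15 of 16 (median 1.65, 1.48 to 1.84). Lce1a1 and Lor stood at 24.1 and 69.5 CPM in the non-lesional T cells, against 32.6 and 86.7 CPM in keratinocytes, so free RNA could not be separated from them. The suprabasal keratins Krt2 and Krt10 were 2.54-fold (2.49 to 2.60) and 1.89-fold (1.86 to 1.93) lower. Cell cycle genes were higher in 10 of 47 and lower in 3 (median 0.37, 0.29 to 0.49), with the kinetochore gene Cenpf 6.23-fold (4.16 to 9.76) and Mki67, a marker of dividing cells, 5.58-fold (3.50 to 9.46) higher and the replication licensing gene Mcm2 2.98-fold lower (2.13 to 4.12). The cell cycle median was 0.00 without cluster 12 and −0.24 from means of cells, and the differentiation median was 0.04 at a clustering resolution of 2.0. The 10 highest genes were Crct1 (36.5-fold, 12.4 to 177), AY036118, Hist1h2ap, Hist1h1e, Cenpf, Mki67, Hist1h2ae, Tnrc6c, Lor (3.74-fold, 2.74 to 5.25) and Krt16. Lowest were Ccer2 (7.75-fold, 7.31 to 8.21), the β-defensin gene Defb6 (4.83-fold, 4.66 to 5.01), Snhg9, Nme2, Slc39a1, Krt2, Pinlyp, Mmp3, Mreg and Aqp3 (2.36-fold, 2.24 to 2.47). Snhg9 and Nme2 were also lower in T cells and ILCs of this pair (15.6 against 46.9 CPM and 71.9 against 244 CPM). Odc1 was 0.686-fold, Srm 0.598-fold, Cebpb 0.796-fold and Sms 1.07-fold the untreated level. Arg1, at 0.788 against 3.96 CPM, was 0.199-fold (0.0684 to 0.616), and on the log2 scale it turned to 0.24 after thinning. S100a8 was at 14.3 against 0.565 CPM (25.4-fold, 4.50 to 1008, against 1 UMI) and S100a9 at 8.90 CPM against 0 (at least 5.25-fold higher). Of 437 untreated keratinocytes, 288 had under 0.1% mitochondrial UMIs, against 1 non-lesional keratinocyte, so the cells differed in quality as well as genotype. The clusters differed too, since 68.6% of untreated keratinocytes lay in cluster 12 (2.40% of non-lesional) and 68.6% of non-lesional keratinocytes in cluster 24 (10.5% of untreated). MHC class II genes were higher in 7 of 7 (median 3.82, 3.39 to 4.20), but they were higher by nearly as much in T cells of the same pair of libraries (3.53, 3.20 to 3.80).

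Lesional whole skin was compared with non-lesional epidermis of the same genotype, the comparison of the lesion. Lesional keratinocytes were higher in 15 of 21 stress keratins and alarmins and lower in 1 (median 1.69, 1.66 to 1.74). Krt6a, a keratin of wounded and hyperproliferative epidermis, was at 1177 against 16.9 CPM (69.5-fold, 60.7 to 79.9), Krt16 was 9.46-fold higher (8.82 to 10.2), and S100a8 and S100a9, which encode the calprotectin alarmins, were 12.96-fold (11.1 to 15.2) and 16.7-fold (13.8 to 20.4) higher. In lesional cells with Xist alone, log2 ratios of S100a8 and S100a9 were 0.27 and 0.10. Cell cycle genes were higher in 25 of 48 and lower in 0 (median 0.73, 0.66 to 0.80), with Mki67 3.84-fold (3.53 to 4.18) and Mcm3 4.06-fold (3.41 to 4.85) higher. Terminal differentiation genes were lower in 17 of 33 and higher in 10 (median −0.83, −0.86 to −0.79).

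The next values cover all lesional keratinocytes, of which 49.6% lay in cluster 29, a hair follicle cluster without non-lesional cells. They do not separate the lesion from this difference of cell populations. Hypoxia targets were higher in 12 of 20 and lower in 1 (median 1.01, 0.90 to 1.14), with the angiogenic factor gene Vegfa 35.4-fold (21.9 to 61.2) and Egln1 7.30-fold (5.99 to 8.96) higher. Glycolysis genes were higher in 9 of 17 (median 0.77, 0.71 to 0.82), with the lactate transporter gene Slc16a3 5.73-fold (4.11 to 8.15) and Pgam1 2.80-fold (2.64 to 2.96) higher. Polyamine and arginine genes were higher in 9 of 21 and lower in 1 (median 0.49, 0.44 to 0.60), with the arginine transporter gene Slc7a1 6.71-fold (5.52 to 8.21) and Azin1 4.45-fold (3.91 to 5.07) higher. Oaz2, encoding an antizyme that restrains ornithine decarboxylase, was 2.76-fold lower (2.44 to 3.13). Odc1 was 3.63-fold (3.28 to 4.02), Srm 1.85-fold (1.70 to 2.03) and Sms 1.06-fold the non-lesional level, and Arg1 was at 0.456 against 0.788 CPM. Genes of the unfolded protein response were higher in 16 of 27 and lower in 1 (median 0.85, 0.77 to 0.94), with the chaperone gene Hspa5 3.51-fold higher (3.36 to 3.67). IL-17, TNF and NF-kB targets were higher in 11 of 24 and lower in 3 (median 0.50, 0.43 to 0.58), with Ccl2 31.5-fold (23.6 to 43.2) and Cebpb 4.25-fold (4.06 to 4.47) higher and Ccl20 6.93-fold lower (5.74 to 8.43). MHC class I presentation genes were higher in 13 of 21 and lower in 1 (median 0.74, 0.69 to 0.79), with H2-Q6 23.1-fold higher (17.1 to 32.0). Cholesterol and lipid synthesis genes were higher in 13 of 27 and lower in 1 (median 0.64, 0.56 to 0.75). In the PP6 holoenzyme list 4 of 5 were higher (median 0.85, 0.70 to 1.01), with Ppp6r1 5.32-fold higher (4.04 to 7.11). Relative to genes of like length the medians were 0.27 for cholesterol, 0.31 for the PP6 holoenzyme and 0.51 for glycolysis. Mitochondrially encoded genes were higher in 8 of 13 (median 0.998, 0.98 to 1.02). Immediate-early and dissociation stress genes were higher in 20 of 35 and lower in 9 (median 0.68, 0.64 to 0.73; 0.44 relative to all genes). MHC class II genes were lower in 7 of 8 and higher in 1 (median −2.20, −2.29 to −2.10; −1.02 after subtracting free RNA). H2-Aa stood at 35.4 against 269 CPM in keratinocytes and at 14.6 against 375 CPM in T cells and ILCs. Free RNA of the non-lesional library could therefore not be separated from this difference. Among differentiation genes, Tgm1, which crosslinks the cornified envelope, was 7.39-fold higher (5.11 to 11.02) and Krt1 2.70-fold higher (2.62 to 2.79). Lce1a1 was 119-fold lower (40.5 to 581) and Tgm3 6.99-fold lower (6.10 to 8.02).

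Hair follicle genes led the 10 highest, which were Krt25 (1412-fold, 685 to 3513), Krt71 (732-fold, 419 to 1417), S100a3, Tchh, Krt6a, Krt35 (log2 ratio −0.00097 without cluster 29), BC100530, the heat shock gene Hspa1b (35.0-fold, 33.3 to 36.8), Gjb2 and Krt28. The 10 lowest were Krt2 (0.182 against 2481 CPM), Ccer2, AY036118, Serpinb7 (38.0-fold), Guca2a, Calm5, Tlx1, Slc4a8, Kazald1 and Il1r2. Of the lesional keratinocytes, 49.6% lay in cluster 29, a hair follicle cluster with 1 cell of the untreated epidermis and none of the non-lesional epidermis, while most non-lesional keratinocytes lay in cluster 24. Within the shared cluster 23 (141 against 120 cells), the stress list stood at 1.35 (1.15 to 1.52), with Krt6a 25.4-fold (20.9 to 31.2) and S100a8 59.6-fold (28.8 to 149) higher. The cell cycle list turned there, with 31 of 49 lower and 1 higher (median −1.33, −1.39 to −1.26), and the differentiation list stood at 0.00. Within cluster 13 (50 against 98 cells) the stress list stood at 1.88 (1.66 to 2.09) and the differentiation list at −0.97. Against untreated wild-type epidermis, lesional keratinocytes had medians of 2.15 (1.96 to 2.29) for the stress list, 0.99 for cell cycle, 0.36 for glycolysis and 0.04 for differentiation. Mitochondrially encoded genes were higher there in 13 of 13 (median 1.86, 1.75 to 1.94). In cluster 23 of that comparison, cell cycle turned to −1.13 (−1.28 to −0.99), with 26 of 49 lower and 1 higher.

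Lesional T cells and ILCs were higher in 30 of 40 effector genes and lower in 6 (median 2.72, 2.53 to 2.90). Il17a was at 718 against 7.22 CPM (99.5-fold, 66.6 to 156), the inhibitory receptor gene Ctla4 at 295 against 0.903 CPM (327-fold, 111 to 1590.1) and the costimulator gene Icos 54.7-fold higher (38.5 to 80.3). Lower members of the list included Prf1 15.2-fold (11.97 to 19.7), Tcrg-C1 9.25-fold (8.56 to 10.0) and Trdc 8.80-fold (8.43 to 9.20). These T cells lay in clusters 9 and 6 in the lesional skin and in cluster 5 in the epidermis, so the populations differed. Lesion, age, tissue layer, barcode set and sex of the cells differed together in this comparison. The body site of both groups is not given, so a difference of site could not be separated from the lesion. In keratinocytes the median of all genes was 0.24 and the ratios rose with transcript length (Spearman 0.41 across genes). The stress list stood at 1.45 relative to all genes and 1.83 relative to genes of like length, and at 0.17 with no minimum of UMIs, which adds members with few UMIs.

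Lesional skin was compared with untreated wild-type dermis for the immune cells of the dermis. Lesional macrophages and monocytes were higher in 25 of 33 inflammatory genes and lower in 1 (median 1.67, 1.51 to 1.85). Chil3 was at 991 against 19.7 CPM (50.3-fold, 34.5 to 76.5) and the protease inhibitor gene Slpi was 51.7-fold higher (30.7 to 94.9). Arg1 was at 93.0 CPM against 0 (at least 42.5-fold higher). In lesional macrophages with Xist, Arg1 stood below its level in imiquimod macrophages (27.4 CPM). The 42.5-fold bound is therefore that of all lesional macrophages, and it is smaller in those with Xist. Mmp12, encoding macrophage elastase, was 52.1-fold higher (34.0 to 84.3). Resident macrophage genes were lower in 13 of 25 and higher in 2 (median −0.86, −0.92 to −0.79). Lists named for other cell types moved in these macrophages as well. Keratinocyte stress and alarmin genes were higher in 11 of 12 (median 1.87, 1.64 to 2.06) and basal keratinocyte adhesion genes in 8 of 10 (median 1.38, 1.02 to 1.71). T cell and ILC effector genes were lower in 11 of 16 and higher in 2 (median −1.33, −1.57 to −1.09). The resident list was also lower in T cells and ILCs of the same pair, in 5 of 8 with 1 higher (median −2.30, −2.61 to −1.92), and complement genes in 3 of 4 (median −2.33, −2.75 to −1.85), with C1qb at 6.83 against 55.2 CPM.

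Among the resident genes, Timd4, a receptor for apoptotic cells, was 98.3-fold lower (16.8 to 3964, with 1 lesional UMI), Ccl24 5.48-fold (4.48 to 6.73) and Selenop 4.42-fold (4.24 to 4.61) lower. By contrast, Retnla (3.97-fold, 3.48 to 4.53) and Lyve1 (3.60-fold, 2.75 to 4.79) were higher. Matrix remodelling genes were higher in 10 of 15 and lower in 1 (median 1.93, 1.61 to 2.13), with the membrane metalloprotease gene Mmp14 24.5-fold (13.2 to 51.4) and Pdpn 12.8-fold (7.39 to 24.3) higher. In lesional cells with Xist the list stood at 0.65. Interferon-stimulated genes were higher in 16 of 30 (median 0.97, 0.84 to 1.11), with Zbp1 7.53-fold higher (3.53 to 19.2). Glycolysis genes were higher in 10 of 16 (median 0.89, 0.78 to 1.003), with the glucose transporter gene Slc2a1 3.20-fold higher (2.06 to 5.21). Hypoxia targets were higher in 6 of 17 and lower in 1 (median 0.85, 0.66 to 1.07), with Hif1a 4.25-fold higher (3.28 to 5.59). The polyamine and arginine list was balanced, with 4 of 23 higher and 4 lower (median −0.06, −0.29 to 0.11). Arg2 was 31.7-fold higher (8.61 to 265) and Odc1 0.432-fold (0.369 to 0.506), Srm 0.947-fold and Sms 0.612-fold the untreated level. Cebpb was 1.77-fold (1.66 to 1.88) and Il1b 3.19-fold (2.84 to 3.58) higher, Il23a 8.79-fold higher (1.39 to 366, against 1 UMI; log2 ratio −0.20 in lesional cells with Xist) and Tlr7 0.399-fold the untreated level. The 10 highest genes were Saa3, Hp, Chil3, Mmp12, Slpi, Arg1, Vcan, Fn1, Mmp14 and Spp1 (14.8-fold, 12.3 to 18.1). The 10 lowest were Bc1, Snhg9, the chemokine genes Ccl7 (12.5-fold, 11.03 to 14.2) and Ccl2 (7.84-fold, 6.93 to 8.90), Ramp3, Dennd5b, Nme2, Tslp, Mcpt4 and Tfrc. Mcpt4 is a mast cell marker, and the free RNA guard did not cover mast cells of the untreated dermis. Bc1, Snhg9 and Nme2 were also lower in T cells and ILCs of this pair, so they are not particular to macrophages. Nme2, for example, stood at 29.6 against 513 CPM there.

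In T cells and ILCs, Il17a was 7.53-fold (5.60 to 10.4), Il17f 8.23-fold (4.86 to 15.1), Ifng 46.3-fold (12.7 to 384, against 2 UMIs) and Ctla4 9.94-fold (5.88 to 18.3) higher. Il22 was not clearly different at 13.2 against 8.49 CPM (1.55-fold, 0.546 to 6.09). Il13, a type 2 cytokine gene, was 23.3-fold lower (10.8 to 57.7), and the effector list had 9 of 40 higher and 4 lower (median 0.27, 0.15 to 0.41). Interferon-stimulated genes were higher in 7 of 21 (median 1.11, 0.80 to 1.45), with Ifi27l2a 8.11-fold higher (4.60 to 15.8). The heat shock gene Hspa1b was at 15166 against 1099 CPM. Within macrophage cluster 0 alone (141 against 213 cells) the inflammatory list stood at 0.92 (0.58 to 1.18) and the resident list at −0.40 (−0.46 to −0.34). Fibroblasts could not be compared, since the untreated dermis held 16, and genotype, lesion, age, tissue layer, barcode set and sex of the cells differed together. Body site, not given for either group, may differ as well.

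Lesional skin was compared with imiquimod dermis to set the psoriasis-like models side by side. Lesional macrophages and monocytes were higher in 23 of 24 resident genes (median 1.46, 1.39 to 1.51), with Retnla at 747 against 0.522 CPM (1429.6-fold, 797 to 2868) and Lyve1 19.5-fold higher (16.3 to 23.4). Mmp12 was 58.4-fold (51.6 to 66.2), Gpnmb 45.2-fold (39.97 to 51.3) and Spp1, encoding osteopontin, 25.4-fold (23.7 to 27.3) higher. Lesional fibroblasts were higher in 33 of 36 extracellular matrix genes (median 1.53, 1.45 to 1.63), and subtracting free RNA turned this to −0.45. The imiquimod fibroblasts also held leukocyte RNA, such as the neutrophil gene Retnlg at 1039 CPM. Oxidative phosphorylation genes were lower in 53 of 73 in fibroblasts (median −0.85, −0.89 to −0.81) and in 49 of 73 in macrophages (median −0.84, −0.88 to −0.80), with 0 higher in either. In fibroblasts, subtracting free RNA turned this to 4.44. The free RNA estimate reached 100% in the imiquimod fibroblasts, so the fibroblast values after subtraction (−0.45 and 4.44) do not settle the direction. Genotype, treatment, age, tissue layer, barcode set and sex of the cells differed together. Body site, not given for the lesional skin, may differ from the ear as well.

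In macrophages and monocytes, inflammatory genes were higher in 15 of 33 and lower in 5 (median 0.66, 0.56 to 0.75). The neutrophil chemoattractant gene Cxcl3 was 16.2-fold higher (14.6 to 17.9) and the fibronectin gene Fn1 5.99-fold higher (5.60 to 6.405). The gene Ccl2 was 3.65-fold (3.26 to 4.09) and the monocyte gene Ly6c2 2.83-fold (2.54 to 3.16) lower, and the list stood at 0.07 with TMM factors. Complement genes were higher in 8 of 10 (median 1.09, 1.03 to 1.16), with C4b 12.04-fold (9.94 to 14.6) and C1qa 2.65-fold (2.57 to 2.72) higher. MHC class II genes were higher in 9 of 13 (median 1.21, 1.12 to 1.28), with Cd86 3.19-fold (2.75 to 3.70). Hypoxia targets were higher in 9 of 17 (median 0.99, 0.78 to 1.14), with Vegfa 9.20-fold higher (7.17 to 11.8). Relative to all genes the medians were 0.58 for hypoxia, 0.25 for inflammatory, 0.68 for complement and 0.80 for MHC class II genes, and hypoxia stood at 0.41 relative to genes of like length. Immediate-early and dissociation stress genes were higher in 27 of 35 (median 0.996, 0.93 to 1.05; 0.59 relative to all genes). Polyamine and arginine genes were higher in 7 of 22 (median 0.42, 0.32 to 0.54). Arg1 was 3.40-fold (2.92 to 3.94) and the polyamine transporter gene Atp13a3 4.49-fold (3.86 to 5.22) higher, with Odc1 at 1.04-fold, Srm at 0.792-fold and Sms at 1.09-fold. The polyamine list stood at −0.09 with TMM factors and Arg1 at −1.55 (log2 ratio) in lesional cells with Xist. Cebpb was 1.71-fold higher (1.66 to 1.76), Il1b 0.980-fold, Il23a 2.08-fold (1.16 to 3.54) and Tlr7 1.43-fold (1.05 to 1.91). The 10 highest genes were Retnla, Mfge8 (62.3-fold, 54.3 to 71.7), Mmp12, Gpnmb, Spp1, Cxcl3, Mmp19, Pdpn, Hspa1b and Cdkn1c. Lowest were AY036118, Wdr89, Ccl12, Ccl7 (4.42-fold), AW112010, Nme2, Ccl2, Aif1, Fpr2 and Clec4a2. Wdr89 and Nme2 were also lower in T cells and ILCs of this pair (74.2 against 337 CPM and 29.6 against 171 CPM). The macrophage populations differed, since 51.8% of lesional macrophages lay in cluster 0, against 0.451% of those with imiquimod. Within monocyte cluster 4 (104 against 1043 cells), the resident list was on the other side (2 of 17 higher, 8 lower; median −1.04, −1.45 to −0.68), and the inflammatory list stood at 0.93 (0.78 to 1.04).

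In fibroblasts, Col1a1 was at 8126 against 1362 CPM (5.97-fold, 5.80 to 6.14), Col3a1 3.64-fold (3.56 to 3.72), Col15a1 52.3-fold (28.3 to 109) and the microfibril gene Mfap4 10.4-fold (9.42 to 11.6) higher. Matrix remodelling genes were higher in 22 of 33 and lower in 5 (median 1.47, 1.27 to 1.59). The protease inhibitor gene Timp3 was 32.5-fold (25.6 to 41.9) and Lrrc15 21.0-fold (13.8 to 33.6) higher. Saa3, encoding an acute phase protein, was 5.48-fold lower (5.41 to 5.54). Complement genes went both ways, with C4b 13.8-fold (12.1 to 15.7) and C3 10.1-fold (9.25 to 11.1) higher and 6 of 14 lower (median 1.17, 1.05 to 1.30). Cell cycle genes were lower in 17 of 26 (median −1.11, −1.24 to −0.996), which subtracting free RNA turned to 2.46. With the free RNA estimate at 100% in the imiquimod fibroblasts, that value does not settle the direction either. The 10 highest genes were Ctla2a (33.8-fold, 28.3 to 40.6), Timp3, Spon2, Sfrp4, Cntn1, the B cell chemoattractant gene Cxcl13 (24.2-fold, 19.1 to 31.1), Col15a1, Clec3b, Tnn and Hmcn2. The 10 lowest were Tyrobp (377-fold, 248 to 602), Fcer1g, Cd52, Coro1a, Alox5ap, Ctss, Gmfg, Spi1, Clec4a2 and Lcp1, all leukocyte genes. The neutrophil gene S100a8 stood at 5935 CPM in the imiquimod fibroblasts against 71012 CPM in the neutrophils of that library. Retnlg, another neutrophil gene, stood at 1039 CPM in these fibroblasts. In that library it stood at 138 CPM in T cells and ILCs, 161 CPM in macrophages and 589 CPM in Schwann cells. Leukocyte RNA counts in the class total of these fibroblasts, and its part in the matrix folds was not tested. The clusters differed, since 84.0% of lesional fibroblasts lay in cluster 14 and 96.3% of imiquimod fibroblasts in cluster 20. The median of all genes was 0.58 in fibroblasts and 0.41 in macrophages, and the ratios rose with transcript length (Spearman 0.60 and 0.59 across genes). In fibroblasts, immediate-early and dissociation stress genes were higher in 28 of 35 (median 1.13, 1.07 to 1.21; 0.55 relative to all genes). Relative to all genes, remodelling stood at 0.89 and complement at 0.58 in fibroblasts, and relative to genes of like length at 0.97 and 0.63. Relative to genes of like length the matrix list stood at 0.85, oxidative phosphorylation at −0.35 in fibroblasts and −0.30 in macrophages, and the resident list at 1.41, against 0.76 (0.64 to 0.91) in lesional macrophages with Xist.

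**Figure D3:**
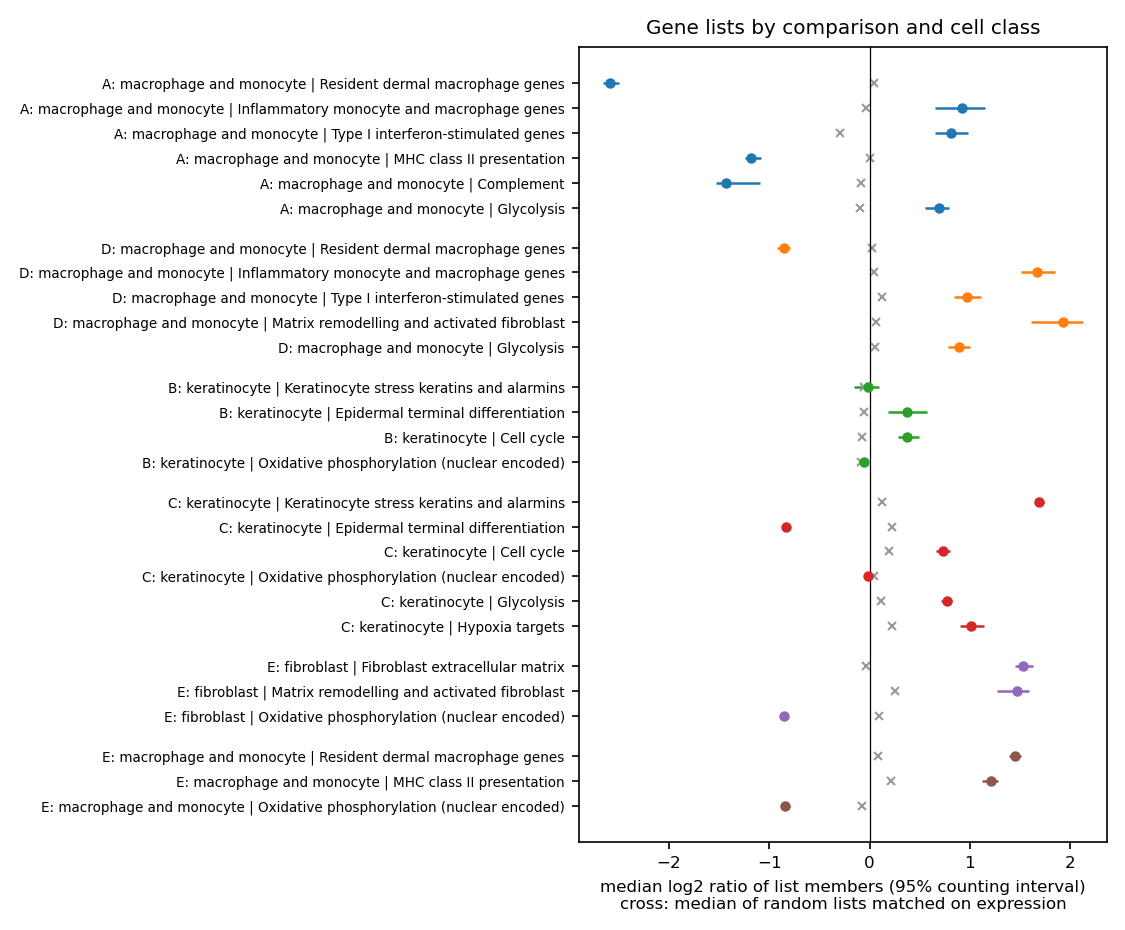
Median log2 ratio of gene lists by comparison and cell class, with 95% counting intervals as bars and the median of matched random lists as crosses; A is imiquimod against untreated dermis, B non-lesional against untreated epidermis, C lesional skin against non-lesional epidermis, D lesional skin against untreated dermis and E lesional skin against imiquimod dermis. Resident macrophage genes stand at −2.58 in A and 1.46 in E, where fibroblast values turn sign when free RNA is subtracted for the matrix (−0.45) and oxidative phosphorylation (4.44) lists. The free RNA estimate reached 100% in the imiquimod fibroblasts, so these turns do not settle the direction.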

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

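Of the tests in this part, those of the library preparation behind the oxidative phosphorylation pattern and of free RNA behind the MHC class II pattern were chosen after the result was seen.

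Xist, the RNA of the inactive X chromosome of females, had 11072 UMIs in the lesional whole skin library, against 0 in the untreated dermis, untreated epidermis and imiquimod dermis and 3 in the non-lesional epidermis. It stood out as a signal outside the main comparisons, which leave out Xist and Y-linked genes. Among lesional cells, 737 had Xist alone, 1076 had Y-linked UMIs alone, 36 had both and 730 had neither, and both kinds occurred in keratinocytes (172 and 183 cells), fibroblasts (161 and 361) and macrophages and monocytes (51 and 117). The library therefore holds cells of at least 1 female and 1 male mouse, which the labels do not state. Cells of 1 sex could carry a difference, and in 5 lists tested on the members measured in all cells the smallest share kept in either set of cells was 0.522 (0.436 to 0.626, resident macrophage genes against imiquimod, in cells with Xist), so for that list the question stays open, while the other kept shares were at least 0.788. The question stays open outside these 5 lists too. In cells with Xist, matrix remodelling in lesional macrophages against untreated dermis fell from 1.93 to 0.65, and the keratinocyte log2 ratios of S100a8 and S100a9 against non-lesional epidermis fell from 3.30 and 3.47 to 0.27 and 0.10.

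Oxidative phosphorylation genes were lower in the lesional than in the imiquimod library in fibroblasts, macrophages and monocytes, T cells and ILCs, dendritic cells, vascular endothelial cells and neutrophils (medians −1.71 to −0.69). A transcript length trend between the libraries may hold the larger part, since random lists matched on length and expression stood at −1.07 to −0.44. In 6 of 6 classes the list lay more than 0.2 below them, which argues against length as the whole cause. The 6 classes come from the same pair of libraries, so they are not independent checks. Matching in 10 length bins also leaves differences of length within a bin. The preparation of the lesional library is argued against as the whole cause too: in 4 of 7 contrasts of that library without the imiquimod library, the list's interval lay above −0.3 (keratinocytes −0.02 and −0.06, macrophages −0.10, dendritic cells −0.04), although T cells stood at −0.74 and −0.75 against the epidermal libraries. Relative to the median of all genes the list was lower in all 7 (−0.62 to −0.20), with its interval above −0.3 in 3, so a part from that preparation stays open. Against untreated dermis, the list was higher in the imiquimod library in macrophages and monocytes (median 0.52), T cells and ILCs (0.59) and dendritic cells (0.54). The shortest of all measured genes had medians of 0.33, 0.41 and 0.44 in the same contrasts, in the same order of classes. The list values here are not corrected for length. Whether a higher level in the imiquimod library beyond the length trend is part of the pattern therefore stays open. The preparation of the imiquimod library was not tested, and it stays open beside the treatment.

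MHC class II genes were higher in keratinocytes of the non-lesional than of the untreated epidermis in 7 of 7. Free RNA of other cells is a candidate explanation, since the genes stood no higher in these keratinocytes than in T cells (median log2 ratio −0.47) or melanocytes (−0.21) of the same library, and Langerhans cells stood 5.96 above the keratinocytes. H2-Aa, for example, had 269 CPM in keratinocytes, 375 CPM in T cells and ILCs, 339 CPM in melanocytes and 16987 CPM in Langerhans cells. Doublets with Langerhans cells are argued against, since the 5% of keratinocytes with the most H2-Aa held 18.3% of its UMIs and 83.0% of keratinocytes had one. Low expression in keratinocytes themselves stays open.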

How the results depend on the processing

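The 5 comparisons, gene lists, naming rule and 14 alternatives were fixed before the data were examined; the alternatives on erythroid cells, the median of all genes, transcript length, Xist cells, Y-gene cells, clusters 12 and 29 and low mitochondrial content were chosen after seeing the data. Of 374 values, 226 had a log2 size of at least 0.58 with an interval off 0, and 8 of these turned direction in 1 setting each, while the others kept it in the settings run for them. For single genes, the pseudocount and the minimum of UMIs could not turn the direction. Named genes had been picked for intervals beyond 2-fold, so the count of turns is no measure of how firm the directions are. Those 8 are Arg1 in keratinocytes of non-lesional epidermis (0.24 after thinning), Krt35 in lesional keratinocytes (−0.00097 without cluster 29, the hair follicle cluster that holds it), Il23a in lesional macrophages against untreated dermis (−0.20 in Xist cells), Arg1 in lesional macrophages against imiquimod (−1.55 in Xist cells), and in lesional fibroblasts against imiquimod, after free RNA was subtracted, the lists of oxidative phosphorylation (4.44), chemokines (1.26), matrix (−0.45) and cell cycle (2.46). The imiquimod library held 1 keratinocyte, so its keratin UMIs count as free RNA and the estimate reaches 100% in its fibroblasts. Subtraction then left only counts above the library's average there, on a smaller total, so those 4 values do not settle the direction. For the others the cause was not tested. Smaller values turned too, such as cell cycle genes in non-lesional keratinocytes (−0.24 from means of cells) and polyamine genes in lesional macrophages against imiquimod (−0.09 with TMM factors).

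Resident genes in imiquimod macrophages (−2.58) stood at −2.12 with TMM factors, −2.27 with a pseudocount of 20 CPM, −2.88 from means of cells, −2.82 after thinning, −2.30 relative to all genes, −2.44 relative to like length and −2.46 with classes from markers alone. Stress genes in non-lesional keratinocytes (−0.01) stood at 0.13 after thinning, −0.18 with the stricter filter, 0.15 with all barcodes and 0.14 at resolution 2.0. Stress genes in lesional keratinocytes (1.69) stood at 1.39 with TMM factors, 1.55 with a pseudocount of 20 CPM, 0.17 with no minimum of UMIs, 1.94 from means of cells, 2.05 after thinning, 1.45 relative to all genes, 1.83 relative to like length, 1.56 in Y-gene cells, 2.04 without cluster 29, 1.60 with all barcodes and 1.78 with no doublet removal. Inflammatory genes in lesional macrophages against untreated dermis (1.67) stood at 1.96 with a pseudocount of 1 CPM, 2.08 from means of cells, 2.29 after thinning, 1.51 in Xist cells (members chosen anew; 1.32 with the members of all cells), 1.99 with the stricter filter, 2.04 with all barcodes, 1.86 with no doublet removal, 1.87 at both other resolutions and 2.17 with classes from markers alone. Matrix genes in lesional fibroblasts (1.53) stood at 0.96 with TMM factors, 1.43 with a pseudocount of 20 CPM, 1.37 from means of cells, 1.34 after thinning, 0.94 relative to all genes, 0.85 relative to like length, 1.78 in Xist cells, 1.68 with the stricter filter and 1.70 with no doublet removal. The neutrophil share of the imiquimod dermis (14.8%) was 11.6% with no doublet removal and 18.6% with classes from markers alone. The log2 ratio of Ppp6c in non-lesional keratinocytes (−0.23) lay between −0.46 and −0.10 in all settings, within its interval. Apart from the free RNA case above and the drop to 0.17, which adds members with few UMIs, the cause was not tested.

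At resolution 0.5 the fibroblast comparison gave no value, since the imiquimod dermis then held 13 such cells. Depth limits the untreated libraries most, where several ratios rest on 1 to 3 UMIs. No paired analysis was possible because each group has 1 library.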

Other observations

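The tests in this part compare values only, and the contrasts named here were chosen after their values were seen.

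T cells and ILCs of the lesional skin and of the imiquimod dermis, which lay in the same clusters 9 and 6, differed in their cytokine genes. Il22 was 238-fold lower in the lesional skin (166 to 356; 13.2 against 3143 CPM), Il17f 10.8-fold lower (9.88 to 11.8), the granzyme gene Gzmb 10.4-fold lower (8.97 to 12.2) and Il13 13.2-fold lower (6.48 to 31.1). Ifng was 4.94-fold higher (3.99 to 6.16), the transcription factor gene Maf 4.76-fold higher (4.26 to 5.34) and Il5 9.47-fold higher (4.71 to 21.6), and the effector list had 19 of 40 higher and 9 lower (median 0.76, 0.65 to 0.86). The median of all genes in T cells was 0.43, and the ratios rose with transcript length (Spearman 0.63 across genes). Vascular endothelial cells (164 against 37 cells) were lower in 35 of 42 cell cycle genes in the lesional skin (median −2.10, −2.35 to −1.90), with Cdk1 22.3-fold lower (12.5 to 42.6). Of 25 endothelial activation genes, 10 were higher and 2 lower in these cells (median 0.23, 0.07 to 0.48), below the median of all genes in these cells (0.40). Higher members included the selectin genes Sele 4.83-fold (3.87 to 6.11), Selp 4.37-fold (3.94 to 4.85), Cxcl10 40.3-fold (15.7 to 149) and Glycam1 at 98.3 CPM against 0 (at least 16.6-fold higher). Inflammatory chemokine and cytokine genes were higher in 3 of 24 and lower in 8 (median −0.85, −1.19 to −0.62).

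Langerhans cells of the lesional skin (42 cells) were higher than those of the non-lesional epidermis (205 cells) in 4 of 5 measured complement genes and lower in 1 (median 1.87, 1.53 to 2.35), with C1qb 26.2-fold higher (14.9 to 50.4) and Cfp 1.91-fold lower (1.58 to 2.32). C1qb stood at 262 CPM in these cells, 2742 CPM in lesional macrophages, 6.83 CPM in lesional T cells and 1.497 CPM in lesional fibroblasts. RNA of macrophages joined to Langerhans cells was not tested, and the non-lesional epidermis had 0 cells classed as macrophages. Their interferon-stimulated genes were higher in 7 of 19 (median 0.89, 0.55 to 1.19), with Slfn5 6.95-fold higher (4.01 to 12.6). T cells and ILCs of the non-lesional epidermis had less of the granzyme gene Gzmb than those of the untreated epidermis (4.50-fold lower, 3.52 to 5.77) and less Il13 (2.36-fold lower, 1.72 to 3.24). Lesional neutrophils (74 cells, against 707 with imiquimod) were lower in the interferon-stimulated genes Ifi27l2a (5.80-fold, 4.16 to 8.34) and Ly6e (4.21-fold, 3.10 to 5.89).

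The barcodes of the lesional library came from another set than those of the other libraries. It shared 0 barcodes with any of them, and 24.4% to 26.4% of the 7-base barcode starts of the other library, where the other libraries shared 83.7% to 100% among themselves. The labels give the same kit for all 5 libraries, so the chemistry used for each library could not be settled. In the untreated epidermis, 55 UMIs of Mptx1 came from 1 keratinocyte.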
